A study of Mus musculus with 7 samples.

How the data were processed

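The samples were 7 ATAC-seq libraries from mouse retinal endothelial cells at postnatal day 6, 3 from early G1 and 4 from late G1, grouped by the sample titles. Per the labels' protocols, retinas were digested with collagenase, living CD31-positive and CD45-negative cells were sorted by reporter colour, and their nuclei were treated with the transposase. Nothing in the labels says whether the libraries of a group came from separate animals. Trimmomatic, STAR, bedtools and MACS2 were used on mm10, per the submitters' processing notes.

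The files used were 2 peak lists, 1 per group. Per the file headers, the authors called broad peaks with MACS2 2.2.7.1 on 1 merged file of paired-end fragments per group, without a control and with all duplicate fragments kept. The cutoffs were a q-value of 0.05 for narrow and 0.1 for broad regions, the background was estimated over 10000 bp, and the effective genome size was 2862010578 bp. A shift of -37 and an extension of 73 bp were given in the command, per the file headers. The signal of a peak is the deposited pileup, the mean number of fragments over its enriched parts, which is not scaled to depth. The fold of a peak is the deposited ratio of pileup to local background. The score used for ranking is the deposited -log10 q-value; its column heading was damaged by a spreadsheet, and it was identified from the column order of MACS2 and because it never exceeded the other -log10 column. These are the authors' values for a pool of libraries, and they were used only to describe, rank or filter peaks within a list. Keeping duplicates lets copies of 1 fragment add to a pileup. A broad call joins neighbouring regions, and without a control the background comes from the same fragments. Mean fragment coverage was 11.0 in early G1 and 10.3 in late G1, and the lowest pileup listed was 19 in both.

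Start positions were taken as counted from 1. No peak ran past a chromosome end and no rows of a list overlapped. The reference was the mouse assembly GRCm38, of which mm10 is the same build, with GENCODE release M21; 21829 protein-coding genes with 54355 start sites were used, and 2647.5 Mb of the assembly is sequenced. Overlap meant at least 1 bp. Chance overlap was taken from 100 rotations of each chromosome's peaks by a random offset, from 20 rotations for promoter genes, and from 10 rotations for shared peaks under alternative settings. A peak's location was that of its centre, in the order promoter (within 1 kb of a start site), exon, intron, intergenic. Start sites are those of protein-coding transcripts, and a promoter peak is any overlap with such a window. Promoter coverage of a gene was sampled at evenly spaced positions within 1 kb of the 5' end of the whole gene, which can differ from those start sites. The lists hold no gene names, so the planned assignment by an author annotation could not be made and its alternative, the nearest start site within 100 kb, took its place; 61.5% of early and 63.0% of late peaks were assigned. Peaks per gene were scaled to equal totals and compared as log2 of late over early with a pseudocount of 1, which understates ratios of genes with few peaks.

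The 19 gene lists, 22 motifs, comparisons and alternative settings were fixed before the data were examined. The lists were arterial, venous, tip cell, retinal barrier, pan-endothelial, Notch pathway, TGF-beta and BMP pathway, G1 to S, S to M, shear stress, AP-1 and immediate early, housekeeping, photoreceptor, progenitor and Müller glia, retinal neuron, astrocyte, pericyte and smooth muscle, blood and microglia, and pigment epithelium. All members were matched by symbol. A list's median was placed among 10000 random lists of the same size matched on total peaks per gene. Genes named were, per list, up to 2 in each direction with the largest ratio and up to 4 with a promoter peak in 1 list only, with the 10 genes in each direction with the largest ratio among those with at least 10 peaks and the 5 strongest peaks found in 1 list only. The text gives a selection of these, and some genes the rule names are not reported here. Motifs were searched as exact consensus words on both strands in the central 200 bp, and ratios have 95% intervals on the log scale. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 list per group there was no test between groups and no p-value.

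The overlap search was checked against direct enumeration, with 0 wrong among 2614 intervals. The motif search was checked against a direct search of random sequence, with 595 matches and no difference. The gene list method was tested on simulated data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. Alternatives were a stricter threshold (the upper part of each list by score), equal numbers of the strongest peaks, a reciprocal overlap of 50%, merged rows, autosomes only, promoters within 3 kb, a pseudocount of 0.5, distal peaks only, unmatched random lists, a 400 bp motif window, and matching on GC content and score. Added after the data were seen were gene body assignment, covered bases per gene, random lists matched on GC content, and peaks over 4-fold enrichment only. Values per library were not analysed here.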

Results

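Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in endothelial cells sorted from the retinas of mice at postnatal day 6. The animals carried the FUCCI reporter, which colours cells by cell cycle phase. Cells positive for the endothelial surface protein CD31 and negative for the leukocyte protein CD45 were divided into unlabelled cells, taken as early G1, and red cells, taken as late G1. There were 3 early G1 libraries and 4 late G1 libraries. Each group is represented by 1 peak list called on its pooled libraries, so no value below has a replicate error, and intervals cover counting error only. The early G1 pool held 137191808 fragments with a mean length of 230 bp, and the late G1 pool held 124693948 fragments with a mean length of 236 bp. The series title names arterial and venous specification as its subject, and the comparison of the 2 lists asks where chromatin differs between endothelial cells in early and in late G1. Coordinates are those of mm10.

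The early G1 list was longer, broader and weaker than the late G1 list. It held 606661 peaks that covered 1071.6 Mb, or 40.5% of the sequenced genome, with a median width of 1334 bp. The late G1 list held 383721 peaks that covered 352.4 Mb, or 13.3% of the genome, with a median width of 681 bp. The median fold enrichment over local background, a value the authors' peak caller assigned to each peak, was 2.09 in the early list and 3.85 in the late list. Only 628 early peaks (0.104%) passed 4-fold enrichment, against 185814 late peaks (48.4%). Each group was a single pool, so this difference in peak width and enrichment cannot be assigned to the cell cycle phase. Among the autosomes, peaks were spread evenly: there were 240.4 early and 150.5 late peaks per Mb, with 242 and 149.6 on chromosome 1 and 241.3 and 151.4 on chromosome 19. Chromosome X was less covered, at 23.0% of its bases in the early list and 9.31% in the late list. Chromosome Y carried 742 early peaks and 5331 late peaks, the reverse of the order on every autosome.

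With all peaks used, most late G1 peaks lay where the early list also had a peak, but only slightly more often than random placement gave. Of the late peaks, 254648 (66.4%, 95% exact binomial interval 66.2 to 66.5) overlapped an early peak by at least 1 bp. After 100 random shifts of the peaks along their chromosomes the share was 60.9% ± 0.0686 (SD over shifts), so the observed share was 1.09 times the shifted share. Of the early peaks, 239120 (39.4%, 39.3 to 39.5) overlapped a late peak, 1.08 times the shifted share of 36.5% ± 0.0382. The lists had 168.8 Mb in common, 1.15 times the 147 Mb ± 0.268 of shifted lists. With the upper part of each list by score, 37.8% of late and 23.1% of early peaks were shared, and with equal numbers of the strongest peaks (191860 per list) 23.3% and 22.6%. Both settings shortened both lists. Over all peaks, this left 367541 early-only and 129073 late-only peaks. Shared late peaks were wider than late-only peaks, with medians of 830 and 532 bp, and had a higher GC content, with medians of 44.3% and 41.7%.

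Promoters of protein-coding genes were over-represented among the shared peaks and, with all peaks used, under-represented among the peaks found in 1 list only. Windows within 1 kb of a start site made up 2.44% of the genome. They held the centres of 4.35% of late shared peaks (4.27 to 4.43), which was 1.79 times the genome share, and of 4.11% of early shared peaks (4.04 to 4.20), or 1.69 times. Among late-only peaks the promoter share was 1.97% (1.89 to 2.05), or 0.808 times the genome share, and among early-only peaks it was 2.10% (2.05 to 2.15), or 0.862 times. With the upper part of each list by score, early-only peaks were above the genome share, at 3.34%, and with equal numbers of the strongest peaks at 3.59%. Introns held 36.0% of late shared and 33.8% of late-only peaks, and intergenic sequence held 56.4% and 61.2%. GC and repeat content moved with the promoter share: random windows matched to the late shared peaks on both lay at promoters in 4.04% of cases, against 4.33% of the matched peaks.

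Coverage at start sites was above that of the surroundings in both lists. In the late list 32.4% of the 21829 genes were covered at the start site, against 14.9% at the flanks of the 20 kb window, a ratio of 2.17. In the early list the values were 62.3% and 43.6%, a ratio of 1.43. Housekeeping genes, used by nearly every cell, had the steepest profile of the groups examined in the late list, with 44.4% of 18 genes covered at the start and 5.81% at the flanks. The 90 genes of the endothelial lists were covered at 30.0% of starts and 17.4% of flanks in the late list. Markers of other retinal cells were the 43 genes of the photoreceptor, progenitor and Müller glia, and retinal neuron lists. These were covered at 27.9% and 15.4%. The late endothelial profile was thus no steeper than that of all genes, with a ratio of 1.73.

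**Figure D1:**
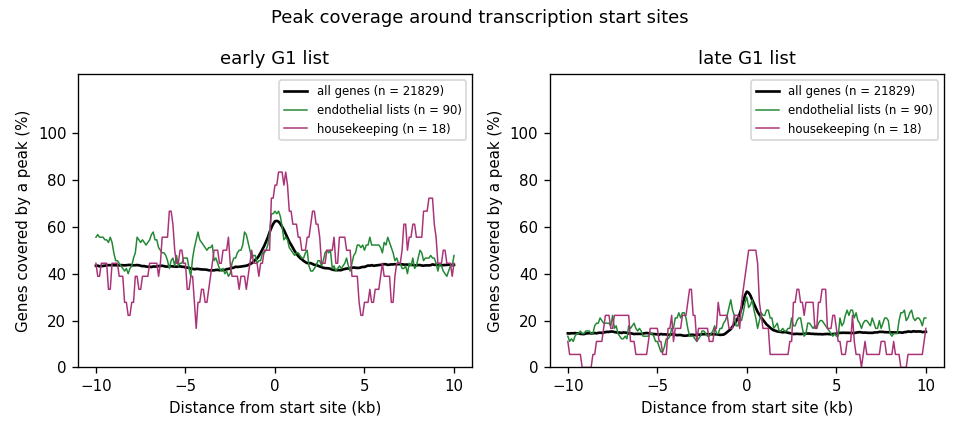
Percent of genes covered by a peak (vertical axis) at each distance from the transcription start site in kb (horizontal axis), for the early G1 list (left) and the late G1 list (right), with lines for all genes, the endothelial lists and housekeeping genes. For all genes, coverage at the start site was 62.3% in the early list and 32.4% in the late list.

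When peaks were ranked by the authors' significance score within each list, promoters lay in different parts of the 2 rankings. In the early list the promoter share was 1.89% in the weakest decile and 4.54% in the strongest decile. In the late list it was 5.01% in the third decile from the weakest, where the median fold was 2.36, and 2.42% in the strongest decile, where the median fold was 12.7 and the median width 475 bp. The strongest late peaks thus lay at promoters at 0.992 times the genome share. Ranks from lists of different lengths show no change between groups.

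**Figure D2:**
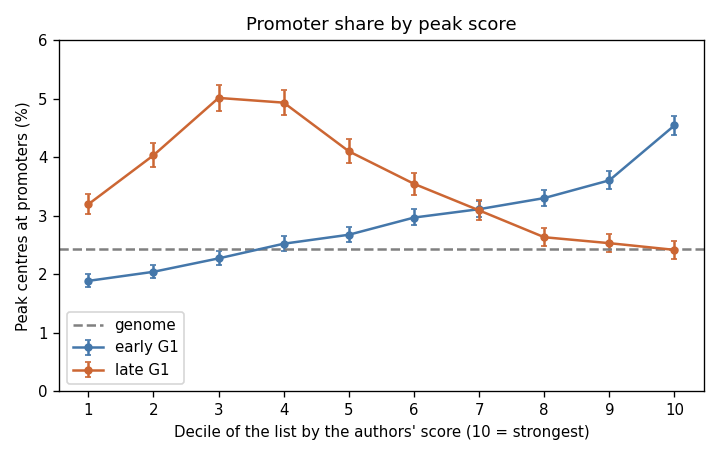
Percent of peak centres within 1 kb of a start site (vertical axis, bars: 95% exact binomial interval) in each decile of a list by the authors' score (horizontal axis, 10 the strongest), for early and late G1, with the genome share as a dashed line. The early share was 4.54% in the strongest decile and the late share 2.42%.

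With all peaks used, most genes had a promoter peak in both lists, and most of the remainder had 1 in the early list only. Of 21829 protein-coding genes, 14035 had a promoter peak in both lists, 6184 in the early list only, 671 in the late list only and 939 in neither. The early list reached 92.6% of genes (92.3 to 93.0), against 85.9% after shifting, and the late list reached 67.4% (66.7 to 68.0), against 51.6%. Genes with a promoter peak in the early list only included Kdr, the main VEGF receptor of endothelium, Ephb4, a venous receptor, Notch4, an endothelial Notch receptor, and Pdgfb, the tip cell ligand that recruits pericytes. Those with a promoter peak in the late list only included Tie1, an endothelial receptor tyrosine kinase, Mmrn2, an endothelial matrix protein, Tgfbr2, the type II TGF-beta receptor, and Col4a2, a basement membrane collagen. Late peaks covered 57.1% of the window at the gene's 5' end for Tgfbr2, 19.0% for Tie1, 4.8% for Col4a2 and 0.0% for Mmrn2. No chance level was computed for genes with a promoter peak in 1 list only. The early list covered 40.5% of the genome and the late list 13.3%, which bears on each early-only call. With equal numbers of the strongest peaks 6609 genes were early-only, 3284 late-only and 3666 in both, and with the upper part of each list by score 5003 were in both.

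With the main settings, no gene list fixed for this tissue stood apart between early and late G1. Peaks were assigned to the gene with the nearest start site within 100 kb. The log2 ratio of late over early peaks per gene was taken after scaling to equal totals. This ratio counts peaks whatever their width, and early peaks were wider, so it is no measure of accessibility. It can run against unscaled coverage: for Notch1 (0.51) early peaks covered 71.4% of the window at the gene's 5' end and late peaks 28.6%. For Ski (0.52) the values were 4.8% and 52.4%, in the direction of its ratio. Arterial, venous, tip cell, retinal barrier and pan-endothelial genes all had medians within the central 95% of 10000 random lists of the same size and total peak number, as did the 14 other lists. Simulated lists of 20 genes with a true log2 shift of 0.58 fell outside the random range of the simulated data in 92% of 50 trials. Those with a shift of 0.32 did so in 46%, and those with no shift in 4%. The simulation split each gene's peaks between the groups by counting error alone. Its rates need not hold for the observed lists, which had 8 to 32 genes. With the main settings every observed median was smaller in size than 0.32. The S to M median was 0.42 with equal numbers of peaks, but -0.05 with the stricter threshold and -0.18 with covered bases. The blood and microglia median was 0.45 with gene body assignment, outside the random range, but -0.25 with the stricter threshold, inside it. Tip cell, Notch pathway and pan-endothelial genes also lay outside that range in at least 1 alternative setting each. The percentiles describe these 2 lists and are no test between groups.

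Among arterial genes 12 of 20 had a ratio above 0, with a median of 0.07 (percentile 78.9). Unc5b, a netrin receptor of arterial and tip cells (chromosome 10, 60762593 to 60831581), had 26 early and 32 late peaks, a log2 ratio of 0.89, and Notch1 had 17 and 16 (0.51). Gja5, the arterial gap junction protein connexin 40, had 42 early and 21 late peaks (-0.36), and Acvrl1, a BMP9 receptor, had 9 and 4 (-0.47). Of the 20 arterial genes 6 had a promoter peak in the early list only, among them Notch4, Efna1 and Igfbp3. The share over all protein-coding genes was 28.3%. Among venous genes 12 of 18 were above 0, with a median of 0.03 (percentile 64.1). Ackr1, a chemokine receptor of venules, had 7 early and 8 late peaks (0.72) and Apoe had 1 and 2 (0.96), while Emcn, the venous and capillary sialomucin endomucin, had 44 and 22 (-0.36) and Ctsc had 46 and 21 (-0.49). Of the 18 venous genes 6 had a promoter peak in the early list only, among them Ephb4, Emcn, Ednrb and Slc38a5.

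Tip cell genes had the highest median of the 19 lists, 0.16, above that of 95% of random lists, with 13 of 20 above 0. The median was 0.32 with the upper part of each list by score, outside the random range, and -0.05 (percentile 38.7) when covered bases replaced peak numbers. Kcne3, a potassium channel subunit of tip cells, had 5 early and 9 late peaks (1.28), while Apln, the tip cell peptide apelin, had 19 and 5 (-1.18) and Kdr had 44 and 23 (-0.30). Ramp3 and Pdgfb were among 6 of the 20 tip cell genes with a promoter peak in the early list only. Retinal barrier genes had a median of 0.05 (percentile 73.7), with 15 of 20 above 0. Fzd4, the receptor of norrin in retinal vessels, had 21 and 20 peaks (0.53) and Mfsd2a, a lipid transporter of barrier endothelium, had 11 and 10 (0.45), while Lrp5, the co-receptor of Fzd4, had 16 and 8 (-0.35) and Lsr had 3 and 1 (-0.61). Pan-endothelial genes had a median of 0.13 (percentile 91.8), with 14 of 21 above 0. Tie1 had 6 and 8 peaks (0.91) and Mmrn2 had 7 and 8 (0.72).

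Notch pathway genes were above 0 in 16 of 20 cases, with a median of 0.14 (percentile 93.2). Mfng, a Notch-modifying glycosyltransferase, had 10 early and 11 late peaks (0.70), and Maml1, a Notch coactivator, had 11 and 6 (-0.22). Dll1 and Nrarp were among 4 of these 20 genes with a promoter peak in the early list only, against 28.3% of all protein-coding genes. The TGF-beta and BMP pathway had a median of 0.05 (percentile 73.6), with 16 of 28 above 0. Ski, a repressor of SMAD signalling, had 20 and 19 peaks (0.52), while the receptors Bmpr1a, with 24 and 7 (-1.07), and Bmpr2, with 23 and 9 (-0.68), had more early peaks. Tgfbr2 had 47 and 37 peaks (0.27). Smad7, Tgfb3 and Bmp4 were among 7 of these 28 genes with a promoter peak in the early list only.

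Cell cycle genes, the lists closest to the sort itself, did not separate the groups. Genes of the G1 to S transition had a median of -0.09 (percentile 10.5), with 13 of 32 above 0 and 18 below. Cdkn2d, a CDK4 and CDK6 inhibitor, had 2 early and 4 late peaks, and Cdt1, the replication licensing factor whose fragment marks G1 in the reporter, had 1 and 2 (0.96). E2f4 had 2 and 0 (-1.41), Mcm7 had 5 and 1 (-1.17) and Gmnn, the licensing inhibitor geminin, had 9 and 3 (-0.81). E2f4, Cdk4, Gmnn and Rbl2 were among 8 of these 32 genes with a promoter peak in the early list only, against 28.3% of all protein-coding genes. Genes of S, G2 and M had a median of 0.16 (percentile 91.6), with 11 of 20 above 0. Top2a had 4 and 8 peaks (1.38), Rrm2 had 18 and 22 (0.87), Aurka had 3 and 1 (-0.61) and Ccnb1 had 7 and 3 (-0.49). Ratios of genes with so few peaks rest on single peaks.

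Shear stress genes had a median of 0.10 (percentile 81.9), with 11 of 17 above 0. Thbd, the anticoagulant receptor thrombomodulin, had 4 and 5 peaks (0.78), Hmox1 had 8 and 9 (0.71), and Map2k5, the kinase above Mapk7 in the flow response, had 26 and 14 (-0.26). AP-1 and immediate early genes had a median of 0.04 (percentile 63.8), with 10 of 18 above 0. Junb had 2 and 3 peaks (0.86) and Fosb had 6 and 2 (-0.75). Housekeeping genes had a median of 0.12 (percentile 84.6), with 12 of 18 above 0. Tubb5 had 2 and 3 peaks (0.86), Tbp had 4 and 1 (-0.92), and Rplp0 had a promoter peak in the late list only.

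Lists for other cells of the retina gave medians in the same range. They were 0.13 for photoreceptor genes (percentile 83.2), -0.05 for progenitor and Müller glia genes (percentile 31.6), -0.03 for retinal neuron genes (percentile 44.0), -0.21 for astrocyte genes (percentile 5.60), 0.14 for pericyte and smooth muscle genes (percentile 81.9), 0.15 for blood and microglia genes (percentile 84.4) and 0.00 for pigment epithelium genes (percentile 52.8). Some signs turned under other settings: with covered bases the astrocyte median was 0.05 and the photoreceptor median -0.22. Pou4f1 and Isl1, transcription factors of retinal ganglion cells, had 34 and 12 peaks (-0.84) and 48 and 18 peaks (-0.76). Their promoter peaks were in the early list only, as for 8 of the 18 retinal neuron genes. Pdgfrb, the pericyte PDGF receptor, had 7 and 8 peaks (0.72) and a promoter peak in both lists. Cx3cr1, a microglial receptor, had 10 and 3 peaks (-0.94). Promoter coverage in the early list was 71.9% of the window for arterial genes and 66.9% for retinal neuron genes, and it was 35.2% for blood and microglia genes. Among unmatched random lists, arterial genes (percentile 98.4), AP-1 and immediate early genes (71.4%, percentile 97.8) and blood and microglia genes (percentile 0.470) lay outside the central 95%. With random lists matched on GC content, chosen after the data were seen, arterial and AP-1 genes lay inside (percentiles 91.6 and 81.2) and blood and microglia genes outside (0.940). TGF-beta and BMP pathway genes, at 53.4%, were inside without matching (percentile 35.1) and outside with it (2.0). In the late list each of these lists lay inside, with and without matching. Without matching, arterial genes were at percentile 75.9, AP-1 genes at 73.9 and blood and microglia genes at 6.7.

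**Figure D3:**
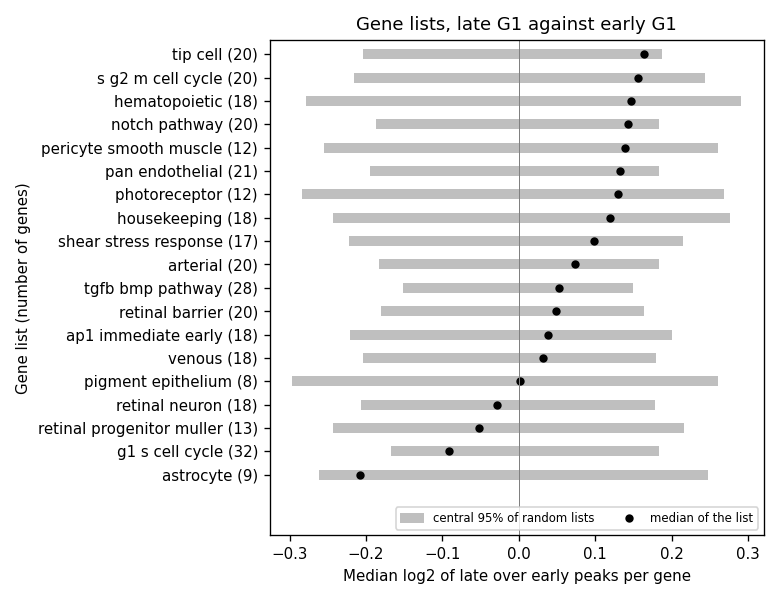
Median log2 ratio of late over early peaks per gene (horizontal axis) for each of 19 gene lists (vertical axis, number of genes in brackets); dots are the lists and grey bars the central 95% of 10000 random lists. All 19 dots lie on their bars, from -0.21 for astrocyte genes to 0.16 for tip cell genes.

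Across 15735 genes with at least 10 peaks over both lists, the 10 most shifted toward late G1 were all on chromosome Y. Gm20890 (ENSMUSG00000100055.1, chromosome Y, 26750605 to 26776799) had 0 early and 18 late peaks. Ssty2, a spermatid gene of the Y long arm, had 0 and 17, and Gm21173, Gm20817, Gm28961, Gm20894, Gm21627, Gm21488, Gm20908 and Gm20883 had 0 early peaks and 14 to 17 late peaks. These genes belong to families with near-identical copies, so the placement of reads among them is uncertain. The genes most shifted toward early G1 were on autosomes. Primpol, a primase-polymerase (ENSMUSG00000038225.15, chromosome 8, 46575594 to 46617212), had 12 early and 0 late peaks assigned to it, although both lists had a peak overlapping its promoter. Aff4, a scaffold of the super elongation complex, had 12 and 1 (-2.26), and Homez had 11 and 1 (-2.15). The exosome subunit gene Exosc3 and Ppig had 10 and 1 each (-2.02). Vmn2r85, Olfr1098, Olfr1245 and Rdh19 were also in this set, from -2.15 to -1.89.

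The strongest peaks found in 1 list only were short. In the early list the first was in an intron (chromosome 6, 103649058 to 103649292), with a pileup of 113444 fragments and a fold of 27.1. The nearest start site was that of Chl1, a neural adhesion molecule, at 48.6 kb. The pileup of this peak lay between those of early peaks on chromosome 2 (823916) and chromosome 9 (66588), against a list median of 26.7. Peaks with such pileups were not removed. Whether this peak reflects a chromatin difference or the placement of reads was not tested. The next early-only peak was intergenic, 15.5 kb from the start of Adgre5 (chromosome 8, 83756760 to 83756991, fold 23.6). Intron peaks lay 2.67 kb from the start of Acacb (chromosome 5, 114173104 to 114173379, fold 20.7) and 16.2 kb from that of Mydgf (chromosome 17, 56199967 to 56200226, fold 15.7). An intergenic peak lay 99.7 kb from the start of Gm8882. Locations were called over all genes, so an intron need not belong to the gene with the nearest start. In the late list the first was at the promoter of Oasl1, an interferon-induced gene (chromosome 5, 114922446 to 114922686), with a pileup of 954.7 and a fold of 22.6. Another was an intron peak 134.3 kb from the nearest start, that of Hpse2 (chromosome 19, 43253923 to 43254172, fold 22.8). The others were intergenic peaks with Cdc34b, Htr1b and Lrfn5 as the nearest genes, at 16.8, 329.1 and 463.3 kb. These 10 peaks were 232 to 276 bp wide, close to 1 mean fragment length.

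The ETS, AP-1, SOX and RBPJ motifs were about as frequent in late-only as in early-only peaks when all peaks were used. The ETS motif, bound by factors that drive endothelial genes, was in the central 200 bp of 0.921% of late-only and 0.871% of early-only peaks, a ratio of 1.06 (95% interval 0.990 to 1.13). Ratios were 0.973 for AP-1 (0.939 to 1.01), 1.03 for SOX (0.986 to 1.07) and 0.979 for the Notch effector RBPJ (0.947 to 1.01). All 4 were near the share of random windows. In late-only and early-only peaks ETS was at 1.08 and 1.02 times that share, and AP-1 at 0.994 and 1.02. SOX was at 1.03 and 1.00 times, and RBPJ at 0.987 and 1.01. Ratios between shares so near the random level cannot show whether the factors were used alike. Of 22 motifs, 7 had an interval that excluded 1. E2F, the family that drives entry into S phase, was at 1.26 (1.07 to 1.48), LHX/VSX at 1.06 (1.03 to 1.09) and RUNX at 1.06 with a lower limit of 1.02. Below 1 were NR2F, the venous factor family, at 0.524 (0.307 to 0.892) on 16 late-only peaks, KLF/SP at 0.920 (0.872 to 0.970), SMAD at 0.936 (0.912 to 0.961) and the neural E-box at 0.970 (0.948 to 0.993). After matching on GC content and score only SMAD, at 0.924 (0.881 to 0.969), and SOX, at 1.09 (1.02 to 1.18), had such an interval. Matching left 57115 late-only and 57115 early-only windows, from 129073 and 367541. KLF/SP (0.997), LHX/VSX (0.991) and the neural E-box (0.987) moved toward 1. RUNX, at 1.071 (0.997 to 1.15), E2F, at 1.204 (0.915 to 1.59), and NR2F, at 0.625, stayed away from 1 with wider intervals. For these, the loss of the interval does not show that GC content or score explains the ratio. NR2F was at 0.838 (0.520 to 1.35) and E2F at 0.949 with the upper part of each list by score. With all peaks used, the E2F motif was in 0.166% of late-only peaks (0.144 to 0.190), near the 0.157% of random windows. In early-only peaks it was in 0.131%, or 0.837 times the random share, so the E2F ratio came mainly from a low early-only share.

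Against random windows, the shared peaks carried more GC-rich motifs. In late shared peaks the NRF1 motif was 2.44 times as frequent as in random windows, the GC-rich SMAD site 1.79 times, CTCF 1.32 times and E2F 1.29 times. The ETS motif was at 1.00 times and AP-1 at 1.04 times the random frequency. In the strongest decile of the late list ETS was in 0.941% of windows (0.847 to 1.04), against 0.853% of random windows. CTCF was in 0.109% (0.0789 to 0.148, 42 windows), 1.17 times the random 0.0934%. Both intervals included the random share. The median GC content of the windows was 44.5% for late shared peaks and 41.5% for random windows.

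**Figure D4:**
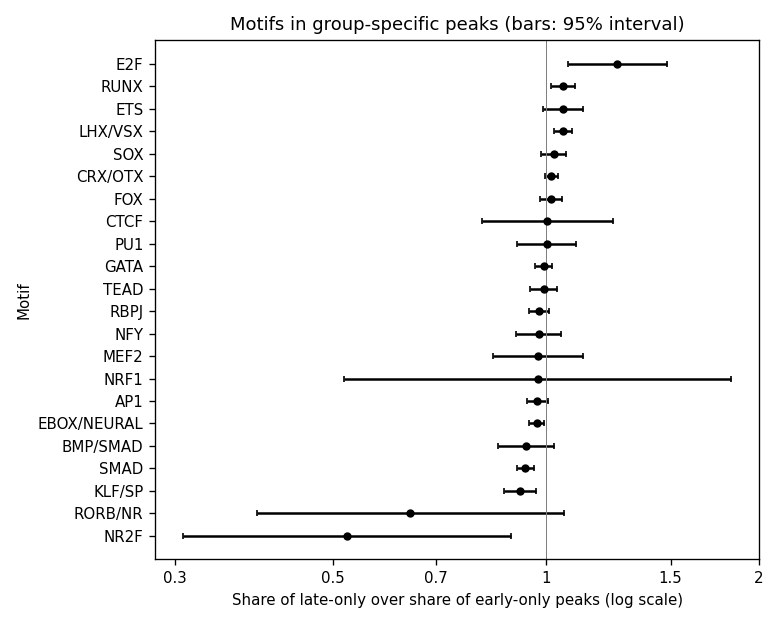
Share of late-only peaks with a motif divided by the share of early-only peaks (horizontal axis, log scale) for each of 22 motifs (vertical axis); bars are 95% intervals for counting error. E2F had the highest ratio, 1.26, and NR2F the lowest, 0.524.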

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

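No paired analysis was possible because the rows of the merged lists name no library, and for the same reason no library was left out in turn. In each list no rows overlapped, so merging rows moved nothing. The shares at 4-fold and the gene list counts with gene bodies, covered bases or GC matching were chosen after the data were seen. By construction, the stricter threshold left 303330 early and 191860 late peaks. Equal numbers meant 191860 peaks per list, so the late peaks were the same in both settings. With the stricter threshold the shared percentages were 23.1 (early) and 37.8 (late), with equal numbers of peaks 22.6 and 23.3, on autosomes 40.1 and 68.3, and with reciprocal overlap 6.80 and 10.7. Over shifted lists the shared percentages were always above 1, at 1.11 and 1.11, 1.13 and 1.13, 1.07 and 1.08, and 1.24 and 1.24 for the same settings in the same order. Promoter genes fell to 10275 (early) and 6950 (late) with equal numbers, and to 6950 (late) with the stricter threshold. Genes with a promoter peak in both lists numbered 5003 with the stricter threshold and 3666 with equal numbers. Early-only promoter genes numbered 9529 with the stricter threshold and 2588 within 3 kb; late-only promoter genes numbered 1947 and 165, and 3284 with equal numbers. The promoter percentages with the stricter threshold were 3.34 (early-only), 2.22 (late-only) and 3.87 (late shared), and with equal numbers 3.59 (early-only), 4.44 (early shared), 2.42 (late-only) and 4.24 (late shared). Early-only peaks thus moved from below to above the genome share of 2.44%, while shared peaks stayed above peaks of 1 list only. Over 4-fold enrichment the promoter percentages were 3.66 (early, on 628 peaks) and 2.73 (late), against 2.89 and 3.55 for all peaks, so the order of these values turned. The early value rests on few peaks and no interval was computed for it, so the turn may be counting error. The number of gene lists outside the random range was 1 with the stricter threshold (tip cell, 0.32), 1 with distal peaks only (Notch pathway, 0.21), 2 with gene bodies (tip cell, 0.26, and blood, 0.45) and 1 with covered bases (pan-endothelial), of 19 each time. With 19 lists, about 1 outside a central 95% is what chance gives. Motif intervals excluding 1 numbered 2 after matching on GC and score and 10 with the 400 bp window, against 7. Matching left 57115 late-only windows of 129073, which widens the intervals. After it KLF/SP (0.997) and the neural E-box (0.987) moved toward 1. RUNX (1.071, against 1.058) and E2F (1.204, against 1.262) kept about the size of their main ratios. With the stricter threshold and equal numbers, intervals newly excluded 1 for the GC-rich SMAD site (0.734 and 0.724) and NRF1 (0.533 and 0.537). The E2F ratio crossed 1 with the stricter threshold (0.949) and with equal numbers (0.960), and LHX/VSX after matching (0.991); the cause was not tested for these or for the other changes. Of the other list and motif values under the alternatives, 102 list medians moved by less than the reach of the random lists (15 of them changed sign; settings that alter only the random lists are not counted), 88 motif intervals still included or excluded 1 as before (19 of their ratios crossed 1), 12 list medians moved further, 10 motif intervals newly excluded 1 and 9 no longer did. Depth per library was not analysed here.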

Other observations

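The genes outside chromosome Y with the highest late over early ratio were looked up after the values were seen. They were Gm17584 (1 early and 14 late peaks, log2 ratio 3.36), Gm17693 (1 and 13, 3.26), Gm10230 (3 and 18, 2.78) and Gm4836 (12 and 27, 1.70) on chromosome X, and Gm14288 (1 and 9, 2.77) on chromosome 2. Some of the strongest peaks lay at the same positions in both lists: chromosome 9, 35305229 to 35305594, had a pileup of 66588 in the early and 75835 in the late list, and chromosome 2, from 98666250 in the early and 98666241 in the late list, had 823916 and 917746. Others did not, such as the early-list intron peak with Chl1 as the gene of the nearest start site.

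The bounds of the tests below were set before their results were seen, except the comparison of chromosome X, which was added afterwards. The decile ratios to matched windows were not set against a bound either.

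The strongest decile of the late list lay at promoters no more often than the genome does. Reads from repeats are argued against: 32.0% of the central windows of these peaks was repeat-masked, 0.927 times the share of random windows. Copies of single fragments may contribute, since duplicates were kept and the median width was 475 bp. These peaks fell on early peaks 1.08 times as often as after random shifts (1.07 to 1.09 over the shifts), between the bounds set for that explanation and against it, so it stays open. For distal elements of endothelial genes, the peaks were assigned to the 90 genes of the endothelial lists 0.881 times as often as other late peaks (0.744 to 1.04). The whole interval lay below the excess set beforehand for that explanation, so no such excess was seen for these genes. It did not meet the stricter bound set against that explanation. Promoter peaks were counted with distal ones, so the test cannot decide on distal elements and the explanation stays open.

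Late G1 peaks were more frequent on chromosome Y. Over the span of 8 single-copy genes of the short arm (725128 to 2170409) there were 19 early and 55 late peaks, 4.62 times the autosomal ratio of late to early (2.74 to 7.79), and over the rest of Y the value was 11.7 times (10.8 to 12.6). The first value met the bound of at least 1.5 set beforehand for a larger part of male cells in the late pool. That bound cannot separate male cells from peak strength. The lowest pileup listed was 19 in both lists, and the median fold was 2.09 in the early and 3.85 in the late list. Where coverage is low, fewer weak peaks reach that pileup, so a late excess could arise without more male cells. More male cells would also lower X relative to autosomes: in peaks per Mb X was at 0.727 in the late and 0.764 in the early list, but in covered share at 0.668 and 0.534, so X does not decide. Multicopy sequence may add to the excess over the rest of Y, which was 2.52 times that over the single-copy genes, also between the bounds.

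Shared peaks lay at promoters more often than peaks of 1 list did. Late shared peaks lay at promoters 1.07 times as often as random windows matched on GC and repeat content, which met the bound set for that explanation. Matching itself raised the promoter share of random windows from 2.51% to 4.04%. Peaks of 1 list only were not matched in this way, and peak width was not matched. The comparison therefore does not show why shared peaks and peaks of 1 list differed. In the strongest decile the ratio to matched windows was 1.23 in the early and 0.938 in the late list, and it was 1.17 in deciles 3 and 4 of the late list. The deciles with an excess were those already seen to have the highest promoter shares of their list. Other deciles were not matched. These ratios are therefore no independent support for an excess, and its biological meaning was not tested.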
